A study of Mus musculus with 4 samples.

How the data were processed

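RNA from 4 mouse-hosted xenografts was hybridised to single-colour (Cy3) Agilent arrays, per the labels, with 2 samples from sunitinib-treated mice and 2 from vehicle-treated mice. The authors deposited 1 value per feature and array on a log2 scale, and limma is named in the submitters' processing notes without a version. The log2 scale was read from the values, which ran from 6.75 to 16.34 with the brightest features at 16. The background correction and the normalization method are not given in the sources used here. The deposited values were already normalized between arrays, since the 25th percentile was 8.70 or 8.71, the median 8.89 or 8.90 and the upper quartile 9.47 to 9.49 on every array. They were used as deposited.

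No detection or saturation flags were used here. Most features sat close to a common floor (5th percentile 8.48 or 8.49), as happens when background is not subtracted, so that log2 differences of dim genes are compressed. A value of 15.95 or more was treated as saturated, which held on all 4 arrays for 135 of 45220 features and 60 genes, and no fold is given for these. Each array carries a single value per feature, so that the number of arrays limits the precision.

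Features were named through the platform annotation table, with symbols updated by gene number in the RefSeq table for GRCm38.p6, which held 99.4% of the listed features. Of the features, 33653 had 1 gene, 56 had several and 11511 were not listed there. Features without a single gene were tested but not named, and control spots among them could not be told apart. Features that shared gene and accession in 8 or more copies (217 probes with 8 to 20 spots) were combined by their median. The median absolute deviation among such spots of a probe had a median of 0.13 to 0.16 log2 on the 4 arrays. A gene was represented by its brightest probe, and of the 107 genes chosen by the rule for named genes, 51 had more than 1 probe and 13 had a probe of the other sign by at least 0.1 log2. For 7 of these that probe was above the median of all genes. This gave 19087 genes and 30654 tested values per array. No columns of per-sample values were left unused.

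Sunitinib was compared with vehicle with lmFit and eBayes in limma 3.58.1 under R 4.3.3, with treatment as the single factor. P-values were adjusted by Benjamini-Hochberg over all 30654 tested values, with a threshold of 0.05. A second, exploratory count took genes with an unadjusted p under 0.01 and an absolute log2 difference of at least 1. Gene lists were tested with camera at a preset correlation of 0.01 and adjusted over 34 lists, and the tests were repeated with an estimated correlation and with fry. The lists held 646 genes, of which 601 had a named probe, and the other 45 (among them Csf1r) are not analysed here. The labels do not say whether replicates were separate animals, so that p-values measure the spread between these samples, which may be technical.

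The design, the gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took genes that passed with the same sign on both slides. A direction with fewer than 12 such genes was filled up to 10 with those of smallest p among genes with an absolute log2 difference of at least 1, the same sign on both slides and a mean above the median of all genes (9.08). It also took the 4 members of smallest p from each list whose test passed, up to 2 from each other list, all measured target kinases, and Vegfa, Pgf, Mki67, Pecam1, Col1a1 and Acta2. Genes named outside this rule are said to be so.

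The array titles place replicate 1 of both groups on 1 slide and replicate 2 of both groups on another, so that the replicate number marks a shared slide and pairs the samples. Deviations from the group means of arrays on the same slide correlated at -0.225 across the tested values. The slide was added as a block as an alternative, and differences are also given within each slide. The block, like leaving out 1 array, left 1 residual degree of freedom rather than 2. A call lost in such a fit does not by itself show that slides or arrays disagreed. In those titles the vehicle arrays are number 1 and the sunitinib arrays number 2 of their slide, so that array number and treatment cannot be told apart.

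The other alternatives were quantile normalization, centring on the median, leaving out probes under the 30th percentile, the mean of all probes of a gene, eBayes with an intensity trend and robust prior, a floor at the 5th percentile, and leaving out each array. After the data were seen, 4 more were added, namely removal of a smooth trend with position on the array (a running median over 21 by 21 features, on a layout of 85 columns and 532 rows inferred from the feature numbers), that removal with the slide block, every spot as its own probe, and a block with crossed replicate numbers.

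The fits were tested on 10 simulated data sets of the same size (30654 values per array for the sunitinib against vehicle comparison, 200 genes changed). They found 46.9% of genes changed by 1 log2, 90.7% of those changed by 2 and 97.7% of those changed by 4, with 7.7 false calls per set. The shifted list was found in 100% of the sets, and 0.1 of 33 unshifted lists was called per set. Simulated genes were drawn independently of each other and without a slide effect. In the real data the correlation estimated within the lists that passed ran up to 0.411. The simulation therefore does not measure how often unshifted lists are called in the real data. The shares of changed genes found also depend on the 200 genes changed per set, and do not give the power in the real data. There Scd1 (2.32) and Adipoq (2.33) did not pass (limma adjusted p = 0.0924 and 0.362), while Xist (-3.26) did. Genes of the shifted list may be among the 7.7 false calls per set. Figures were drawn with matplotlib.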

Results

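Gene expression was measured in xenografts of MDA-MB-231, a human triple-negative breast carcinoma cell line, carried by immunodeficient mice. Of the 4 tumour samples, 2 came from mice given sunitinib, an inhibitor of the VEGF, PDGF and related receptor tyrosine kinases, at 40 mg/kg/day, and 2 from mice given vehicle. The arrays carried mouse probes, which read the host cells of the tumour (vessels, fibroblasts, immune cells, fat) and any human transcript that binds the same probe. The series title speaks of sunitinib withdrawal, and the labels do not state when the samples were taken relative to the last dose. Each sample gave 0.5 µg of RNA with a RIN number of 9. The 45220 features correlated across features at r = 0.980 between the sunitinib arrays, 0.984 between the vehicle arrays, and 0.970 between the arrays that shared a slide, on both slides. Between arrays of different group and slide it was 0.979 (sunitinib replicate 1 with vehicle replicate 2) and 0.970.

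The first comparison asked which host genes differed between sunitinib-treated and vehicle-treated tumours. Xist, the noncoding RNA that coats the inactive X chromosome in female cells, fell by 3.26 on the log2 scale (SE 0.08, n = 2 per group, limma adjusted p = 0.0149). It read 12.19 and 12.26 in the vehicle arrays and 8.97 and 8.96, near background, in the sunitinib arrays. Eif2s3y, a translation initiation factor subunit encoded on the Y chromosome, read 10.21 and 10.02 with sunitinib against 8.46 and 8.58 with vehicle (difference 1.60, SE 0.11), without passing (adjusted p = 0.362). Of the genes that did not pass, Scd1, a fatty acid desaturase, had the smallest adjusted p (difference 2.32, SE 0.10, adjusted p = 0.0924).

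Xist was the 1 gene of 19087 that passed in limma, with 0 genes higher, while 2661 genes had an unadjusted p under 0.05 where chance alone gives 954, and 1211 to 2630 did so without 1 array and 1793 with the slide as a block. The exploratory threshold took 46 genes, of which 16 were higher and 30 lower. This balance rested on single arrays, with 15 higher and 145 lower without sunitinib replicate 1 and 20 higher and 14 lower without sunitinib replicate 2. All 4 Xist probes were lower in both sunitinib arrays than in both vehicle arrays. Y-linked genes other than Eif2s3y, examined after the values were seen, lay near background, with brightest probes of Zfy1 at 0.15, Uty and Kdm5d at 0.10, Zfy2 at -0.02 and Usp9y at -0.23. Kdm5c, an X-linked gene that escapes inactivation, read 0.44 higher on its brightest probe and -0.16 on another, while Ddx3x (-0.10) and Kdm6a (0.11), which also escape it, differed little on theirs. Eif2s3x, the X-linked copy of Eif2s3y, read 1.11 higher (SE 0.08) on its brightest probe, and its next probe, almost as bright, differed by -0.02. Xist lost its call with the slide as a block (adjusted p = 0.546, 0 genes called, 30 past the exploratory threshold), with the mean of its 4 probes (-1.56, adjusted p = 0.239) and without any 1 array (adjusted p = 0.42 to 0.625). Its difference stayed at -3.26 with the block and at -3.22 to -3.30 without 1 array, and it passed with the block once the position trend was removed (adjusted p = 0.0266).

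Among other genes with higher values, Cyp2f2, a cytochrome P450, differed by 1.09 (SE 0.14), and Dgat2, which makes triglycerides, by 1.14 (SE 0.15). On the lower side, Pdgfrl, a secreted relative of the PDGF receptors, read 11.55 and 11.13 with sunitinib against 13.08 and 13.15 with vehicle (difference -1.78, SE 0.16). Oaf differed by -1.40 (SE 0.18), Prss3, a trypsinogen, by -1.36 (SE 0.10), and Lrrn4cl by -1.12 (SE 0.13). Ppa1, an inorganic pyrophosphatase, differed by -1.05 (SE 0.08), and Arpc2, a subunit of the Arp2/3 actin nucleator, by -1.04 (SE 0.12). The myosin phosphatase subunit Ppp1r12a (-1.07) and the splicing factor Smndc1 (-1.04) each had a second probe of the other sign (0.38 and 0.10). None of these passed (adjusted p = 0.362 for each).

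The second comparison asked whether groups of genes moved together. Of 34 gene lists, 9 passed in camera with the preset correlation, 4 upward and 5 downward. None passed with an estimated correlation (camera adjusted p = 0.731 or more) or with the directional test of fry. With an estimated correlation, camera rests on the 2 residual degrees of freedom of the fit, so that a pass was hard to reach. The ribosomal protein list had an estimated correlation of -0.0184, below the preset 0.01, and its camera p still rose from 0.00622 to 0.0898. Not passing there therefore does not show that a list was unshifted. The mixed test of fry, which asks whether genes change in either direction, gave an adjusted p of 0.00837 for antigen presentation and oxidative phosphorylation, 0.0354 for proliferation, adipocytes and ribosomal proteins, and 0.0384 for Notch. Xist and Eif2s3y parted the same arrays as the treatment did, so that every list shift is also a difference between arrays with and without Xist.

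Genes of adipocytes, the lipid-storing cells of fat tissue, rose as a list (median log2 difference 0.53 over 17 measured genes, camera adjusted p = 7.72e-10). The adjusted p was 0.731 with an estimated correlation. Of the 17 genes, 15 were higher on both slides, 10 passed upward when adjusted over the list alone (8 with the slide as a block), and 0 passed over all genes tested. Adipoq, the fat cell hormone adiponectin, read 11.41 and 11.23 with sunitinib against 9.28 and 8.70 with vehicle (difference 2.33, SE 0.21). The lipid droplet proteins Plin4, Cidec and Plin1 differed by 2.27 (SE 0.21), 2.06 (SE 0.34) and 1.19 (SE 0.14), and fatty acid synthase, Fasn, by 1.58 (SE 0.14). Outside the rule for named genes, Car3, a carbonic anhydrase of fat and slow muscle, had the largest difference of the list (2.62, SE 0.49). Other members, chosen like Car3 after their values were seen, differed little on their brightest probes. Fabp4, a fatty acid binding protein, was at 0.17, lipoprotein lipase, Lpl, at -0.21 and the hormone Lep at 0.10. With the mean of all probes of a gene, however, Fabp4 passed adjusted over the list alone. The list median was 0.45 on slide 1 and 0.77 on slide 2.

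**Figure D1:**
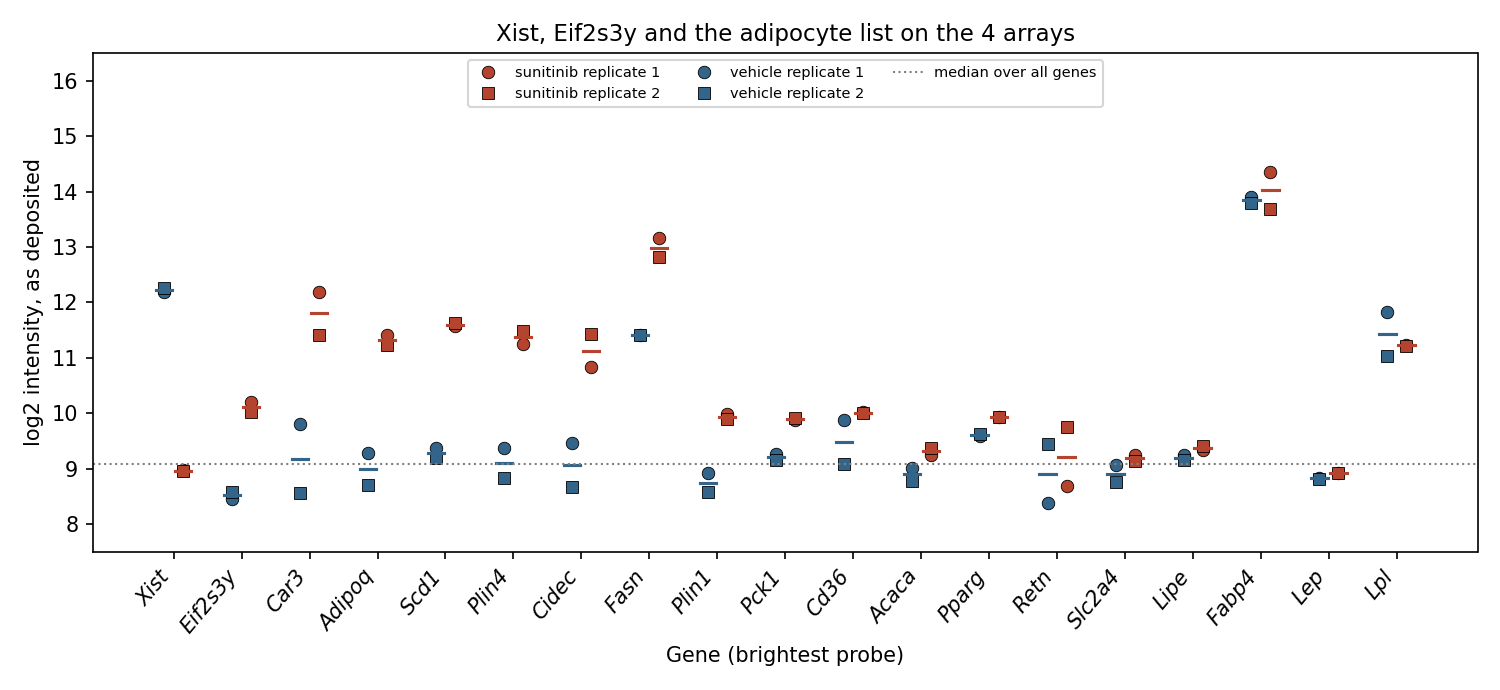
Deposited log2 intensity (vertical axis) of Xist, Eif2s3y and the 17 adipocyte genes (horizontal axis) on each of the 4 arrays, with bars at the group means (n = 2 each) and a dotted line at the median of all genes. Xist and Eif2s3y part the groups in opposite directions, Scd1, Adipoq and Plin4 are higher in both sunitinib arrays, and the arrays of both groups overlap in the brightest probes of Fabp4 and Lpl.

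Cell division genes rose as a list (median 0.28 over 31 genes, camera adjusted p = 3.36e-08, and 0.731 with an estimated correlation). Of these, 25 were higher and 1 lower on both slides, and 9 passed upward when adjusted over the list alone (0 with the slide as a block), with 0 over all genes. The median was 0.165 with the mean of all probes of each gene, and the list still passed. Cdc20, an activator of the anaphase-promoting complex, read 13.64 and 13.73 with sunitinib against 12.98 and 13.03 (difference 0.68, SE 0.08). The helicase subunit Mcm7 differed by 0.53 (SE 0.08), the kinetochore motor Cenpe by 0.46 (SE 0.08) and the mitotic kinase Plk1 by 0.45 (SE 0.09). Mki67, the gene of the Ki-67 proliferation antigen, differed by 0.31 (SE 0.08). The list median was 0.27 on slide 1 and 0.24 on slide 2.

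Interferon-induced genes rose as a list (median 0.27 over 24 genes, camera adjusted p = 4.77e-06, and 0.731 with an estimated correlation). On both slides 20 of them were higher and 0 lower, although 0 passed adjusted over the list alone or over all genes in the main fit. With arrays centred on the median, Ifit3 and Mx1 passed over the list alone. Ifit3 differed by 0.55 (SE 0.10), the antiviral GTPase Mx1 by 0.57 (SE 0.11), Ifit2 by 0.48 (SE 0.11) and the ISG15 protease Usp18 by 0.34 (SE 0.10). The slide medians were 0.23 and 0.28. Antigen presentation genes rose by a smaller median of 0.15 over 16 genes (camera adjusted p = 0.0123, and 0.731 with an estimated correlation), with slide medians of 0.20 and 0.10. The 4 that passed adjusted over the list alone (0 with the slide as a block), with 0 over all genes, were the class II genes H2-Ab1 (0.47, SE 0.08), H2-Aa (0.41, SE 0.08) and H2-DMb1 (0.44, SE 0.11) and the immunoproteasome subunit Psmb9 (0.37, SE 0.08). Second probes of H2-Ab1 and H2-Aa went the other way (-0.22 and -0.48), and that of H2-Aa was almost as bright (mean 13.18 against 13.48). With the mean of all probes, H2-Aa differed by -0.035 and 0 genes passed adjusted over the list alone, while the list still passed (camera adjusted p = 0.0325). The list call ended without sunitinib replicate 1 (median 0.10) and with every spot as its own probe (median 0.115, camera adjusted p = 0.0697).

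Genes of fibroblasts and fibrillar matrix fell as a list (median -0.32 over 28 genes, camera adjusted p = 9.11e-06, and 0.731 with an estimated correlation). On both slides 19 were lower and 1 higher, with slide medians of -0.43 and -0.30, and 0 passed adjusted over the list alone (0 to 12 under the alternatives, among them 2 with the slide as a block, 5 with the mean of all probes and 12 with that block and the position trend removed) or over all genes. Lox, which cross-links collagen, differed by -1.02 (SE 0.22) and the proteoglycan biglycan, Bgn, by -0.995 (SE 0.24). Col5a2, a fibrillar collagen chain, differed by -0.58 (SE 0.12) and the microfibril protein Mfap5 by -0.54 (SE 0.10). The main fibrillar collagens gave little information, because Col1a2 was saturated on every array and Col1a1 lay at or close to saturation on all of them, so that no fold is given for either.

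Hypoxia-induced genes (median -0.30 over 29 genes, camera adjusted p = 0.000234) and glycolysis genes (-0.26 over 16 genes, adjusted p = 0.00425) fell as lists, each with an adjusted p of 0.731 with an estimated correlation. At the median the fall lay on slide 1, where the values were -0.69 and -0.67, against 0.08 and 0.11 on slide 2. Both lists held Hk2, Slc2a1, Ldha, Pgk1, Aldoa, Tpi1, Gapdh, Pfkl and Pgam1. These are most of the measured glycolysis genes, so that the shifts of the lists are not separate results. Hk2, the inducible hexokinase, differed by -1.38 (SE 0.37), Hk1 by -0.88 (SE 0.25) and the glucose transporter Slc2a1 by -0.68 (SE 0.23). On slides 1 and 2 these were -0.95 and -1.80 for Hk2, -0.48 and -1.27 for Hk1, and -1.07 and -0.28 for Slc2a1. Of the 6 probes of Hk1, 3 dimmer ones went the other way (0.29, 0.205 and 0.175). Higd1a (-0.92, SE 0.16), Lox and the Myc antagonist Mxi1 (-0.30, SE 0.08) were the hypoxia genes of smallest p. Vegfa, the ligand of the VEGF receptors, differed by -1.18 on slide 1 and 0.03 on slide 2. In both lists 0 genes passed adjusted over the list alone or over all genes in the main fit. Over the hypoxia list alone, Higd1a passed with arrays centred on the median, and Higd1a and Lox did with a trended, robust prior. The calls ended without sunitinib replicate 1, where the hypoxia and glycolysis medians shrank to -0.015 and -0.01 (adjusted p = 0.183 for both), and without vehicle replicate 1 (-0.135 and -0.0975, adjusted p = 0.0875 and 0.297). Without sunitinib replicate 2 the medians were -0.54 and -0.483.

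Immediate early genes, which respond within minutes to growth factors, fell as a list (median -0.28 over 19 genes, camera adjusted p = 0.0152, and 0.826 with an estimated correlation). On both slides 12 were lower and 2 higher, 0 passed adjusted over the list alone or over all genes, and the slide medians were -0.33 and -0.10. Junb differed by -0.56 (SE 0.13), Egr2 by -0.49 (SE 0.13), Ier3 by -0.81 (SE 0.25) and Jun by -0.28 (SE 0.09). The call ended without sunitinib replicate 2, where the median was -0.225 (adjusted p = 0.164), and without vehicle replicate 1, where it shrank to -0.0425 (0.541). Without vehicle replicate 2 the median was -0.475 (adjusted p = 1.07e-05). Ribosomal protein genes passed downward (camera adjusted p = 0.0235, and 0.731 with an estimated correlation) with a mean of -0.18 but a median of 0 over 30 genes and on each slide, since 12 of them were saturated on all arrays. Rpl27 (-1.10, SE 0.10), Rps24 (-0.76, SE 0.10) and Rpl30 (-1.87, SE 0.36) were among 5 that passed downward adjusted over the list alone (0 with the slide as a block), with 0 over all genes. Dimmer probes of Rps24 and Rpl30 went the other way (0.10 and 0.13). No fold is given for Rps4x, another of the 5, because it was saturated in vehicle replicate 1. That call ended with the mean of all probes (adjusted p = 0.262) and without vehicle replicate 2 (0.115).

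**Figure D2:**
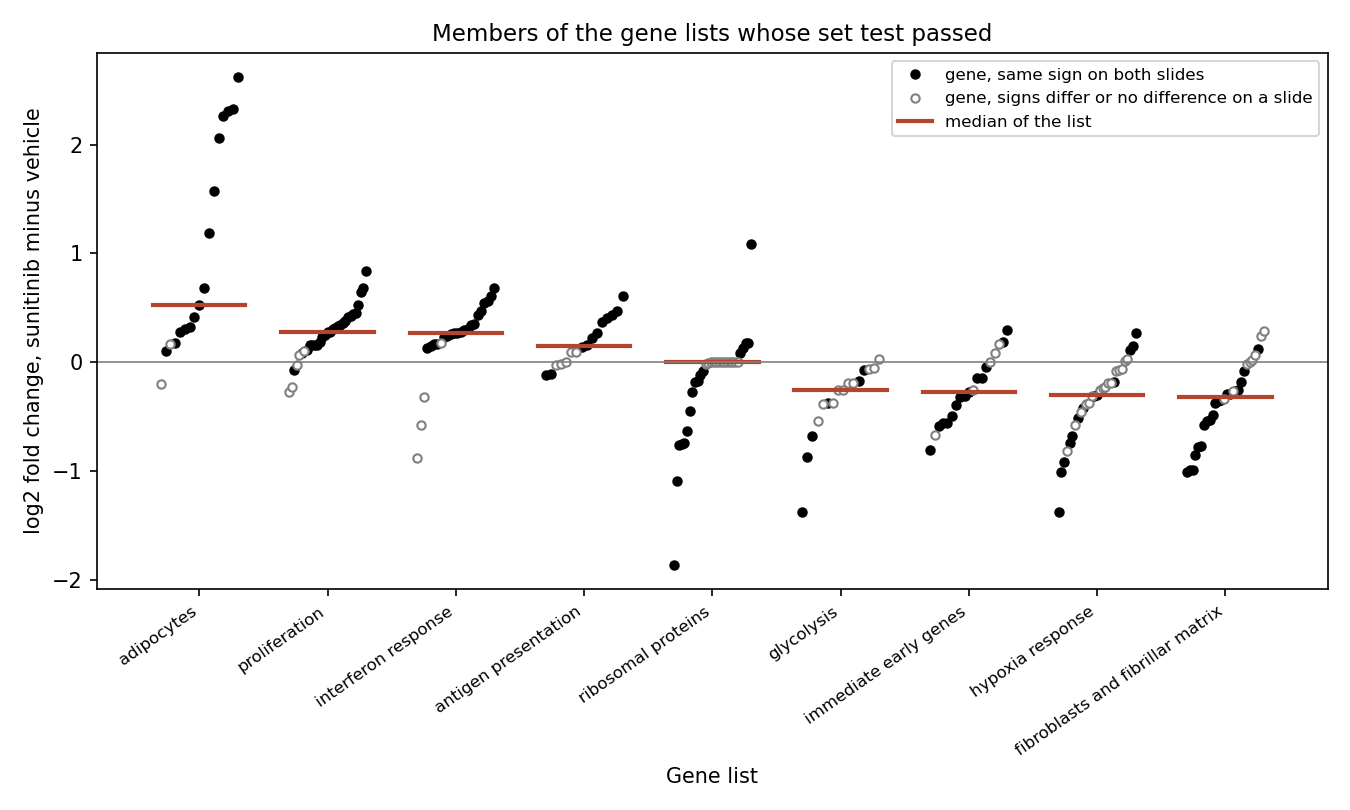
Log2 difference, sunitinib minus vehicle (vertical axis), of each member of the 9 lists that passed in camera (horizontal axis), as filled points where the sign was the same on both slides and open points otherwise, with a line at the list median. Adipocyte genes spread up to 2.62, the proliferation and interferon lists cluster at 0.28 and 0.27, and 12 saturated ribosomal genes lie at or near 0.

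Lists of vessel markers did not pass. The blood vessel endothelium list had a median of -0.01 over 35 genes (camera adjusted p = 0.794), with slide medians of 0.12 and -0.17. Pecam1, the endothelial adhesion molecule CD31, differed by 0.11 (SE 0.10), and by -0.16 on a dim probe. Vwf, the von Willebrand factor of endothelial cells, was the 1 member that passed adjusted over the list alone (0 with the slide as a block), with 12.02 and 11.85 against 12.70 and 12.63 (difference -0.73, SE 0.10), and 0 passed over all genes. The endothelial transcription factor Sox7 differed by -0.37 (SE 0.14). Genes of sprouting tip cells (adjusted p = 0.405), lymphatic endothelium (0.147), pericytes and smooth muscle (0.563) and angiogenic ligands (0.211) did not pass. Downward calls appeared for lymphatic endothelium without vehicle replicate 1 (adjusted p = 0.0225), and for pericytes (0.0291) and angiogenic ligands (0.016) without vehicle replicate 2. Kcnj8, a potassium channel of pericytes, differed by -0.995 (SE 0.26), Acta2 by -0.06 (SE 0.34), the receptor Unc5b by -0.53 (SE 0.15), Vegfc by -0.31 (SE 0.11) and Pgf by -0.24 (SE 0.18).

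Immune cell lists did not pass either. The adjusted p was 0.794 for macrophages, 0.604 for neutrophils and immature myeloid cells, 0.712 for inflammatory cytokines and chemokines, 0.643 for natural killer, T and B cells, 0.712 for mast cells and 0.577 for dendritic cells. The neutrophil list passed downward without sunitinib replicate 2 (adjusted p = 0.0462). Il1b, the gene of interleukin 1 beta, read 11.04 and 11.14 with sunitinib against 11.62 in both vehicle arrays (difference -0.52, SE 0.08). It was the 1 gene that passed adjusted over the neutrophil list alone (0 with the slide as a block), with 0 over all genes. The eosinophil chemokine Ccl11 differed by -0.94 (SE 0.19), Cd14 by -0.71 (SE 0.25) and the integrin Itgax by 0.77 (SE 0.25).

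Among matrix and signalling lists, basement membrane (adjusted p = 0.0938), matrix proteases and inhibitors (0.0719), TGF-beta response (0.139) and the Notch pathway (0.794) did not pass. The receptor Tgfbr2 (-0.55, SE 0.09) and the ligand Tgfb3 (-0.63, SE 0.12) passed adjusted over their list alone, as did the Notch ligand Jag1 (-0.94, SE 0.13) over its own, with 0 over all genes, and none of these did with the slide as a block. The protease list passed downward with dim probes left out (adjusted p = 0.049). Without vehicle replicate 2, the protease (adjusted p = 0.000973) and TGF-beta (0.0136) lists passed downward. With the position trend removed, both and the basement membrane list did (0.00439, 0.0323 and 0.0383). The cholesterol synthesis list (0.283), with Msmo1 at 0.47 (SE 0.11), oxidative phosphorylation (0.183), heat shock (0.94) and the unfolded protein and integrated stress response (0.688) did not pass. Of the heat shock genes, Hspd1 (0.50, SE 0.10) and Hsph1 (-0.81, SE 0.12) passed in opposite directions adjusted over the list alone, also with the slide as a block. The cholesterol list, with Msmo1, passed upward without sunitinib replicate 2 (0.00814) and with the position trend removed (0.0383), and oxidative phosphorylation did without vehicle replicate 1 (0.0443). Markers of skin and mammary epithelium (0.577), nerve and Schwann cells (0.688), red blood cells (0.604) and carcinoma keratins and tumour cell genes (0.509) did not pass. Skeletal muscle genes did not pass (0.577) but did upward with the slide as a block (adjusted p = 0.0484) and without vehicle replicate 1 (0.00112), with slide medians of 0.01 and 0.33.

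**Figure D3:**
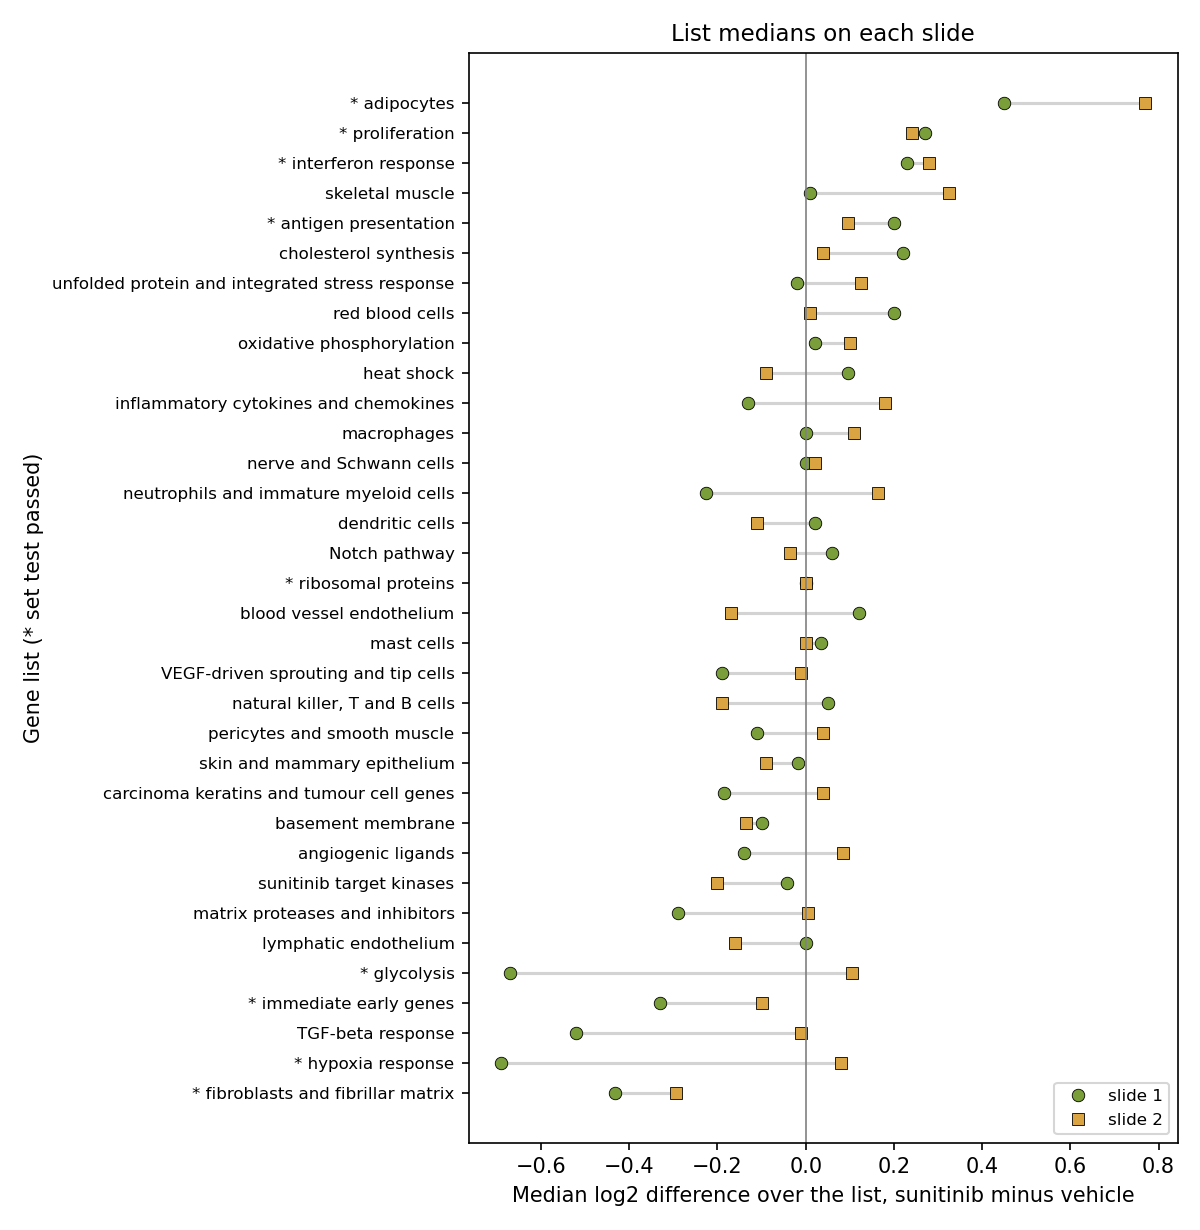
Median log2 difference, sunitinib minus vehicle (horizontal axis), of each of the 34 gene lists (vertical axis), with circles for slide 1 and squares for slide 2 and asterisks at the 9 lists that passed. The adipocyte, proliferation, interferon and fibroblast medians keep their sign on both slides, and the hypoxia median is -0.69 on slide 1 and 0.08 on slide 2.

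The third comparison concerned the transcripts of the receptor tyrosine kinases that sunitinib inhibits. The PDGF receptors had the lowest differences. Pdgfrb, carried by pericytes and fibroblasts, read 13.39 and 12.12 with sunitinib against 14.06 and 14.01 with vehicle (difference -1.28, SE 0.43). Pdgfra, carried by fibroblasts, read 9.84 and 9.89 against 10.98 and 10.32 (difference -0.79, SE 0.23). The VEGF receptors Kdr and Flt1 differed by -0.06 (SE 0.18) and 0.25 (SE 0.12), and the lymphatic receptor Flt4 by -0.16 (SE 0.09). Flt4 lay near background (8.89 to 9.14 on the arrays). With the position trend removed, Flt1 and Flt4 differed by only 0.10 and -0.04.

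Of the 8 measured kinases, 0 passed adjusted over the list alone or over all genes, 2 had an unadjusted p under 0.05, and the list did not pass in camera (adjusted p = 0.191). Kit (0.01, SE 0.09), Flt3 (-0.16, SE 0.08) and Ret (0, SE 0.08) were within 2 standard errors of no difference, with Flt3 and Ret near background. Without 1 array the difference ran from -0.645 to -1.915 for Pdgfrb and from -0.455 to -1.115 for Pdgfra. Without sunitinib replicate 1, Pdgfrb passed adjusted over the list alone (adjusted p = 0.00327), and without vehicle replicate 2 Pdgfra did (0.0175).

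**Figure D4:**
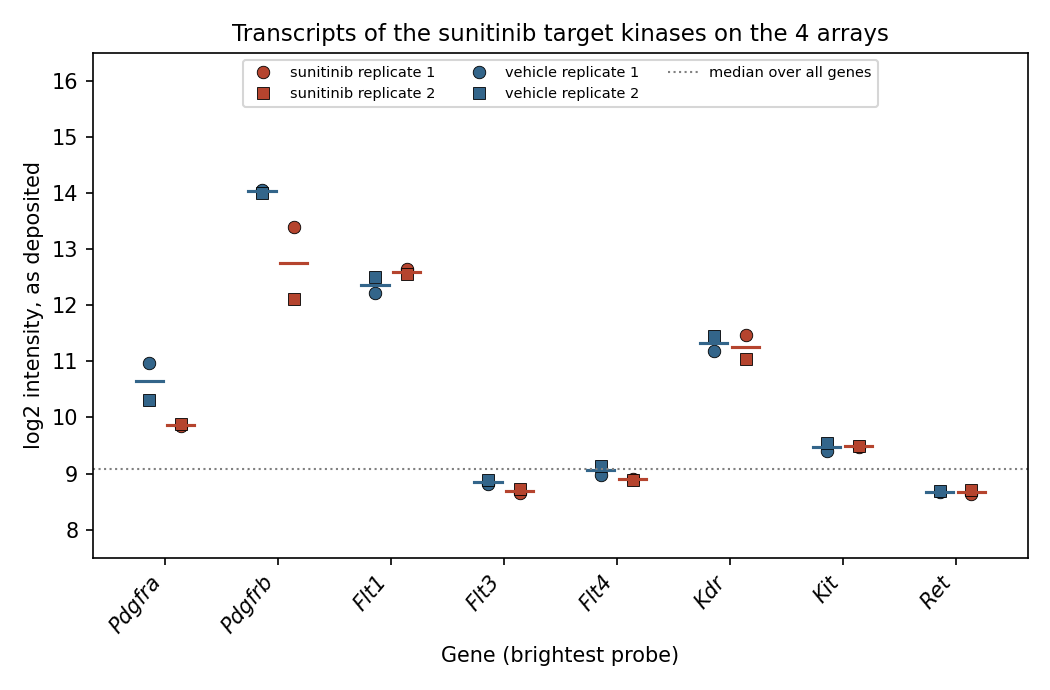
Deposited log2 intensity (vertical axis) of the 8 measured sunitinib target kinases (horizontal axis) on each of the 4 arrays, with bars at the group means (n = 2 each) and a dotted line at the median of all genes. Pdgfra and Pdgfrb lie lower in both sunitinib arrays, Kdr overlaps, and Flt3 and Ret lie at about 8.7 to 8.9 in every array.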

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

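Of the tests in this part, the one on a second set of fat cell genes was specified before its result was seen, and the others after. No group of 2 samples is large enough for a test of outlying samples.

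Xist lay near background in both sunitinib arrays, while Eif2s3y stood above background only there. A fall of Xist brought about by the drug in mice of 1 sex would leave Eif2s3y unexplained, which was 1.60 log2 higher with sunitinib, and an exchange of single samples or 1 wrong label is argued against by the gap of 3.22 between the groups in Xist, against at most 0.07 within a group. Female vehicle hosts and male sunitinib hosts could account for both genes, but the Eif2s3y difference of 15.1 standard errors is part of the observation that raised the question and is no separate support. Other genes did not settle this. Y-linked Kdm5d (0.10) and Usp9y (-0.23) lay near background in all arrays, so that their differences say little. Of 10 probes of Y-linked genes without Eif2s3y, 5 were higher in both sunitinib arrays than in both vehicle arrays, which held for 25.9% of all genes. X-linked genes that escape inactivation are read from both X chromosomes of female cells, so male sunitinib hosts would be expected to lower them. Eif2s3x and Kdm5c, which escape it, were instead 1.11 and 0.44 higher with sunitinib on their brightest probes. On their next brightest probes they differed by -0.02 and -0.16. Kdm6a was at 0.11 and Ddx3x at -0.10, with their dimmer probes at -0.325 and 0.135. Host sex stays open. An exchange of both groups' labels would not by itself make the groups differ in Xist. It would only change which treatment goes with which Xist level, and it was not tested. If the hosts differed in sex, that difference cannot be told apart from treatment here.

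The second pattern lay in features where 1 array stood more than 3 log2 above the other 3, as a speck of dust could produce. At 23 of 23 such features the array on the same slide was the lowest, and the array of the same group the highest, of the other 3 (3.83 expected by chance, exact binomial p = 1.27e-18, two-sided). The test was specified after the values were seen and takes features of the same 4 arrays as independent, so that its p is no separate support. A bright spot on an array normalized by itself would leave the other arrays in no fixed order, so the share of 100% argues against that account. The values may instead have been adjusted for slide and treatment together before deposit, which was not tested. Against the array of the other group and slide, the array on the same slide was lower (median -1.22) and the one of the same group higher (median 0.53). Skeletal muscle genes still differed between the slides (median 0.77), which a full removal of slide differences would not leave. If the values were so adjusted, p-values without a slide block would be too small. The blocked fit called 0 genes, but so did the block with crossed replicate numbers, and the Xist difference stayed at -3.26 with the slide block. The count of 0 therefore cannot decide the question.

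The third pattern was the adipocyte list. A trend with position on the array is argued against as its whole cause, since the list median was 0.50 with the trend removed and 0.53 before. More fat tissue in the sunitinib samples could account for Adipoq, Plin1, Plin4 and Cidec. A second set of 21 fat cell genes gave a set test p = 0.0288 upward, and 0.263 with an estimated correlation. The median was only 0.16, 9 were higher and 4 lower on both slides, and 0 passed adjusted over the set alone. Members on both sides had means below the median of all genes (9.08), where differences are compressed. Among them were Adig (8.71), Aqp7 (8.86) and Klb (8.77) of the lower genes, and Ces1d (8.92), Cidea (8.78) and Trarg1 (8.94) of the higher. The small median is therefore a weak test, and more fat tissue stays open. Host sex stays open as well, because 0 arrays had an Xist level unlike that of their group. An effect of sunitinib on fat cells or on lipid synthesis was not tested apart from these.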

How the results depend on the processing

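The slide block was planned, and the removal of the position trend, the spots taken singly and the crossed block were chosen after seeing the data. The count of 1 gene became 0 with the replicate block (slide) and 30 rather than 46 genes then passed the exploratory threshold; it was 0 with the mean of all probes, 2 with arrays centred on the median, 2 with the position trend removed and 3 with a trended, robust prior, where Scd1 (adjusted p = 0.0151) and Eif2s3y (0.0428) joined Xist. It was 0 without any 1 array, where the lone sample is assumed to vary like the other group, and the exploratory count then ran from 34 to 160, the latter without sunitinib replicate 1. With the position trend removed the exploratory genes were 17 higher and 22 lower. The 9 lists became 0 with an estimated correlation and with the directional test of fry, 6 to 12 without 1 array, and 14 with the position trend removed and the slide block. The adipocyte, proliferation, interferon and fibroblast lists passed under all of the alternatives run with the preset correlation. Their sizes moved with array position, however. With the position trend removed, the proliferation median shrank from 0.275 to 0.195 and the interferon median from 0.27 to 0.194. The fibroblast median went from -0.318 to -0.409 and the adipocyte median from 0.525 to 0.501. Target kinases that passed adjusted over the list alone numbered 0, and 0 to 1 without 1 array. The block ended the call of Xist, added that of the skeletal muscle list and left the other list calls as they were. Of genes that passed adjusted over their list alone, it kept 8 of 10 adipocyte genes, both heat shock genes and none of the rest. It left 1 residual degree of freedom rather than 2, so that p-values also rose where the slides were alike. Cenpe differed by 0.46 and 0.45 on the slides, and its limma p went from 0.0031 to 0.0115. A block with crossed replicate numbers called 0 genes and 10 lists, with 49 genes past the exploratory threshold (29 higher, 20 lower). Most of the 107 named genes were chosen for a small p in these same arrays, so that their direction under alternatives was largely fixed in advance. Of 1387 values of the named genes under alternatives, 1363 kept their direction. Those that did not belonged to Ret, Kdr, Kit, Flt3, Acta2, Pecam1, Col1a1, H2-Aa and H2-Ab1. The cause was not tested. Because signal over background was low for most features, small changes in dim genes were not measurable here.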

Other observations

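A few genes outside the fixed lists were chosen for low values after these were seen, without a test of what they have in common, and did not pass (adjusted p = 0.362 for each). Thbs4, a matrix thrombospondin, read 11.07 and 9.73 with sunitinib against 13.71 and 12.72 with vehicle (difference -2.82, SE 0.56). The matrix protein Fndc1 differed by -2.05 (SE 0.34), Igfbp5, a binding protein of insulin-like growth factors, by -2.21 (SE 0.48), and Cilp, a cartilage matrix protein, by -1.67 (SE 0.35). The lymphatic chemokine Ccl21c differed by -2.65 (SE 0.60) and the clock-controlled factor Dbp by -1.84 (SE 0.33).

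Skeletal muscle genes differed between the slides. Of 20 genes, 15 were higher in both arrays of slide 1 than in both arrays of slide 2, which held for 9.47% of all genes, and the median difference between slides was 0.77. Ckm, the muscle creatine kinase, read 9.07 and 9.14 on slide 1 and 8.27 and 8.23 on slide 2. On slide 2, 6 of these genes lay below the 5th percentile of all features in both arrays, and on slide 1, 0 did.

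The difference between treatments also varied with the position of a feature on the array. Over 95 blocks of 28 rows by 17 columns, the block median ran from -0.22 to 0.21.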
